A study of Mus musculus with 5 samples.

How the data were processed

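Liver RNA of 5 groups of mice was hybridised to Phalanx Mouse OneArray slides in 1 colour (Cy5), with 1 array per group. Per the labels, wild-type (WT) C57BL/6 mice were given chow, a high-fat diet, or the high-fat diet with nordihydroguaiaretic acid (NDGA) at 2.5 g per kg of food, and leptin-deficient ob/ob mice were given chow or chow with the same dose of NDGA, for 16 weeks. Per the series' design text, RNA of 3 animals was used in each group; whether it was pooled before labelling is not given in the sources used here. Each group therefore has 1 column of values and no replicates, so no test, p-value or error can be computed for any gene, and every difference is between 2 arrays.

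The deposited values are linear probe intensities, as judged from the values themselves: they run from below 0, which marks a subtracted background, to a pile-up above 65000 at the limit of the scanner. The authors' scanner, background correction and any scaling are not given in the sources used here. The deposited intensity medians were 38.8 for WT on chow, 39.6 for WT on high-fat diet, 47.0 for WT on high-fat diet with NDGA, 38.1 for ob/ob on chow and 71.0 for ob/ob on chow with NDGA, so the arrays had not been brought to a common level. Between 45.1% and 54.1% of probes lay below an intensity of 50, and 16 to 60 probes per array were at or above 65000.

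Of the 29922 probes, 21020 carried 1 gene symbol in the platform table used here, 0 carried several, and 8902 were unnamed here. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6: 17558 were current, 3410 were replaced through a unique synonym and 52 were kept. This gave 16637 genes, 3566 of them with several probes; each gene was represented by its probe with the highest mean over the 5 arrays.

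Before the data were examined, it was fixed that values would be quantile normalized between the 5 arrays if the column medians differed by more than 0.1 on the log2 scale. They differed by 0.46, so quantile normalization was used. The plan named a log2 scale without an offset. Because deposited values lay below 0, log2(value + 50) was taken, with the offset chosen after the values were seen; differences and folds are on that scale and understate the change of dim genes. A gene counted as expressed in a comparison when the mean of the 2 arrays was at or above the median over all genes, which left 8319 genes; where comparisons were set against each other, the mean of all 5 arrays was used instead, which also left 8319, and numbers shared by chance come from the genes passing there. Genes with a log2 difference of at least 1 (2-fold) were counted.

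A total of 33 gene lists with 701 entries, 580 of them named on the array, were fixed in advance. For each list with at least 5 expressed members, the median difference relative to the median of all expressed genes was set against 10000 random lists of equal size drawn from 20 bins of mean expression. A list is said to stand apart when its median lay outside the central 99% of the random lists, which chance alone would give for 1.24 of the 124 list comparisons if genes were independent; co-regulated genes make it more frequent, and the percentile describes these arrays only. After the data were seen, 4 lists were added: skeletal muscle markers (48 genes), olfactory receptor genes (689 named), keratin genes, and a second set of receptors and defensins foreign to liver (vomeronasal, taste and trace amine receptors and beta-defensins, 137 named). Each fixed list was also set against members of the other fixed lists, which was likewise chosen after the data were seen.

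The genes named here follow a rule fixed in advance: the 12 highest and 12 lowest expressed genes of each comparison; up to 4 expressed members with the largest difference in each list that stood apart or that concerns lipid, bile acid, glucose, lipoxygenase or xenobiotic metabolism; Lep and Ppara; and up to 10 genes per direction that were at least 2-fold apart in both NDGA comparisons. Not all genes that the rule allows are named. Other genes are said to be chosen after their values were seen. Probes saturated on both arrays of a comparison, such as those of Scd1 and Cyp4a10, were not ranked.

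There were 7 alternatives planned in advance: the deposited values without normalization, median centring, a loess of the difference on mean brightness (span 0.3), no filter, a filter at the 75th percentile, the mean of all probes of a gene, and a floor at the 25th percentile. Another 4 were added after the data were seen: an offset of 16, leaving out saturated probes, leaving out the muscle genes, and the background of other fixed lists. List medians are relative to all genes, so for them no normalization and median centring are the same test. The floor left the median over all fixed list genes unchanged. The alternatives counted beside a list are therefore not independent checks. The steps were tested on simulated data for ob/ob against WT: with an assumed noise of 0.2 (SD, log2), 197 of 200 genes changed 4-fold were recovered among 8319 and 1 unchanged gene was called. Among 20 simulated lists per size, 0 stood apart with no shift, 13 with a shift of 0.25 and 20 with a shift of 0.5. The simulation gave each probe independent noise, no shift between arrays, and changes in brighter genes only. On the real arrays the SD per probe was 0.29 in this comparison and up to 0.47 in the others. The simulated rates of false calls therefore do not carry over to these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No genome positions are given, because the build behind the probes is not given in the sources used here.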

Results

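Liver gene expression was measured in lean, diet-obese and leptin-deficient mice with and without nordihydroguaiaretic acid (NDGA), a plant lignan from the creosote bush that inhibits lipoxygenases and acts as an antioxidant. The series' title concerns the effect of NDGA on hepatic lipid metabolism and the share of it that runs through PPAR-alpha, the nuclear receptor that drives fatty acid oxidation in liver. There were 5 arrays, 1 for each of WT on chow, WT on high-fat diet, WT on high-fat diet with NDGA, ob/ob on chow and ob/ob on chow with NDGA. There are no replicates, so every value below is a difference between 2 arrays whose spread between mice is unknown. For genes with 2 bright probes, the differences of both probes correlated at r = 0.31 to 0.37 across genes, and the SD per probe was 0.29 to 0.47 on the log2 scale.

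The ob/ob mouse lacks functional leptin, the fat cell hormone encoded by Lep. Its probe read an intensity of 5.76 to 15.8 on all 5 arrays, near background, so in liver it checks no label. Ppara, which encodes PPAR-alpha, read between 448 on ob/ob chow and 936 on ob/ob chow with NDGA. Its log2 differences were 0.30 for high-fat diet, -0.32 for NDGA in WT, -0.22 for ob/ob against WT and 0.14 for NDGA in ob/ob; without normalization the latter pair was at -0.42 and 0.99.

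High-fat diet against chow in WT mice asks what diet-induced obesity did to the liver. Markers of macrophages, of scar-forming stellate cells and of the acute phase response were higher on the high-fat array, together with lipid droplet and peroxisomal fatty acid oxidation genes. Lcn2, an iron-binding acute phase protein, was 11.5-fold higher (log2 difference 3.52, intensity 52.1 on chow and 1131 on high-fat diet). Col1a2 and Col3a1, which encode fibrillar collagens, were higher by 2.39 and 2.69, although the mean over both probes of Col3a1 was 1.39. Cidec and Cidea, which promote the fusion and growth of lipid droplets, were higher by 1.97 and 1.68. Hsd3b5, a male-specific steroid enzyme of liver, was lower by 4.82 log2 units (-4.82, intensity 10382 on chow and 329 on high-fat diet), and Cyp2b9, a female-biased cytochrome P450, was higher by 3.29.

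In the macrophage and Kupffer cell list, 5 of 13 expressed markers were at least 2-fold higher and 0 lower (median 0.76). They included Mpeg1 (1.54), Adgre1 (1.25), Marco (1.25) and Cd14 (1.17). The stellate cell and fibrosis list had 5 of 14 at least 2-fold higher (median 0.65), with Vim at 1.65 and Col4a1 at 1.21. Acute phase proteins had a median of 0.62; Lcn2 and Mt2 (1.86) were at least 2-fold higher, whereas the fibrinogen chains Fgb (-1.31) and Fgg (-1.24) were lower. Interferon response genes had a median of 0.36 (0.17 without the filter on dim genes) with none of 16 at least 2-fold apart; Gbp3 was at 0.98 and Ifi27 at 0.90.

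Peroxisomal beta-oxidation genes had a median of 0.65, led by Decr2 (1.29), Crot (0.93) and Abcd3 (0.87). The mitochondrial list had a median of 0.38 and stood apart under only 4 of 10 alternatives, not without normalization, median centred or after loess, with Hadh at 1.38 (0.57 as the mean of its probes) and Acadl at 0.91. Fatty acid synthesis genes had a median of 0.34, with Aacs at 1.01, Fads1 at 0.80 and Pklr, the liver pyruvate kinase, at -0.64. In the lipid droplet and triglyceride synthesis list (median 0.35, or 0.13 with the mean of probes), 5 of 20 were at least 2-fold higher, including Mogat1 (1.42) and Plin4 (1.27). Lists that did not stand apart still held large differences. Cyp2c29 (-2.12) and Ces2a (-1.23) were lower and Alas1, which controls heme synthesis, was higher (1.27) among CAR, PXR and AHR targets, Gstm3 (1.65) and Srxn1 (1.63) were higher among NRF2 targets, and Slco1a1, a male-biased organic anion transporter, was lower (-1.57). G6pc (-0.95) and Pck1 (-0.92), enzymes of glucose production, were also lower.

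In all, 177 genes were at least 2-fold higher and 111 lower of 8319 expressed genes, and 8 of 31 lists stood apart as higher and 0 as lower. Olfactory receptor genes, which liver does not use, had a median of -0.30 over 161 expressed, and the second set of foreign receptors and defensins had -0.35 over 21. Without the filter on dim genes both were at -0.06. Probes without a liver target that passed the filter thus differed between these arrays in the direction opposite to the lists. Set against members of the other fixed lists, only the peroxisomal, macrophage and stellate cell lists remained higher, and male-biased genes (median -0.31) stood lower. Bcl3 (4.01), Plau (3.67), Usp37 (3.40), B3galt6 (3.10) and Fam83h (2.92) were among the highest genes, but each rested on a probe at least 4-fold brighter on the high-fat array than on any other. As means of their probes, Usp37 was at 1.78 and B3galt6 at 1.64.

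NDGA on the high-fat diet against high-fat diet alone asks what NDGA changed in diet-obese WT liver. Macrophage, stellate cell, acute phase, interferon and endoplasmic reticulum stress genes were lower with NDGA. The fatty acid oxidation lists did not stand apart (medians -0.04 mitochondrial, 0.09 peroxisomal, 0.23 other PPAR-alpha targets), nor did bile acid genes (-0.28), but single members were higher. Lcn2 read 175 with NDGA against 1131 without (log2 difference -2.48) and Col3a1 366 against 1545 (-2.03). Ehhadh, a peroxisomal beta-oxidation enzyme, was higher by 1.34, Cyp4a14, a fatty acid hydroxylase, by 1.13, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.53. Many of the highest genes were those of skeletal muscle: Ckm, the muscle creatine kinase, was higher by 4.69 (intensity 1501 against 11.7), Cox6a2 by 4.34 and Ckmt2 by 4.13. Nip7 (4.53; 1.48 as the mean of its probes), Spata2 (3.66) and Tmem134 (3.15), which are not muscle genes, ranked among them, each on a probe at least 4-fold brighter on this array than on any other.

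Of 13 expressed macrophage markers, 5 were at least 2-fold lower with NDGA and 0 higher (median -0.77): among them were Mpeg1 (-1.46), C1qb (-1.15), Csf1r (-1.12) and Cd68 (-1.07), the latter pair at -0.55 and -0.48 as means of their probes. The stellate cell list (median -0.52) had 4 of 15 at least 2-fold lower, with Vim at -1.52, Col1a2 at -1.46 and Col4a1 at -1.21. Unfolded protein and integrated stress response genes had a median of -0.70, or -0.27 without the filter on dim genes; the chaperones and folding factors Creld2 (-1.58), Sdf2l1 (-1.35), Pdia4 (-1.20) and Pdia6 (-1.20) were lowest. Interferon genes (median -0.38) had 4 of 17 at least 2-fold lower: Gbp3 (-1.33), Igtp (-1.26), Ifi27 (-1.15) and Isg15 (-1.10). Acute phase proteins had a median of -0.45, endothelial markers -0.45 (-0.29 at the weakest alternative), with Lyve1 at -0.93 and Stab2 at -0.78, and NRF2 targets -0.30 (apart under 6 of 10 alternatives), with Gstm3 (-1.20), Srxn1 (-1.12, or -0.91 as the mean of its probes) and Hmox1 (-1.09) at least 2-fold lower. Beside these decreases, olfactory receptor genes had a median of 0.50 and the second foreign receptor set 0.52, or 0.13 and 0.09 without the filter on dim genes. Skeletal muscle markers had a median of 1.50, with 17 of 28 expressed at least 2-fold higher. Their median was 0.55 without the filter and 0.53 with the filter at the 75th percentile. Of all 47 muscle markers named on the array, dim ones included, 19 were at least 2-fold higher.

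Lipid genes went both ways. Tkfc (-1.61), Acly (-1.09), which makes cytosolic acetyl-CoA, Mlxipl (-0.76), which encodes ChREBP, and Fasn, the fatty acid synthase (-0.72), were lower, and the fatty acid synthesis list had a median of -0.20. Cpt1a, the gatekeeper of mitochondrial beta-oxidation, was at 0.75 and Acads at -0.68, with a list median of -0.04. The other PPAR-alpha targets had a median of 0.23; Fabp3 (2.67) and Cpt1b (0.70) in that list are also muscle genes. Cidea was higher with NDGA (1.13), in the same direction as with the diet. Apoa4, an apolipoprotein, was at least 4.89-fold lower (log2 difference -2.29), a bound because its probe was saturated on the high-fat array. Serpina12, an adipokine of the serpin family, was lower by 4.27 (-4.27; -2.16 as the mean of its probes). Cyp1a2, the main AHR-controlled cytochrome P450 of liver, was at -1.49, and among lipoxygenase and eicosanoid genes the largest difference was that of Alox5ap, the partner protein of 5-lipoxygenase (-0.66).

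In all, 75 genes were at least 2-fold higher and 130 lower, and 0 lists stood higher and 7 lower. Without normalization the counts were 92 and 92. Against the members of the other fixed lists, the macrophage, stellate cell and stress response lists remained lower.

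ob/ob against WT on chow asks how genetic obesity changed the liver. Male-biased liver genes were lower as a list. The sex of the mice was not used in any comparison here, and whether it was the same in both groups was not checked. Hsd3b5 was lower by 5.30 (-5.30) on a probe at least 4-fold brighter on WT chow than on any other array, and Susd4 (-3.29), Cyp7b1 (-2.86) and Nudt7 (-1.48) were lower with it; 6 of 11 expressed male-biased genes were at least 2-fold lower and 0 higher (median -1.36, or -0.46 without the filter on dim genes). Female-biased genes had 4 of 10 at least 2-fold higher (median 0.56, from 0.20 without the filter to 1.21 with the stricter filter): Cyp2b9 (3.48), Cyp2b13 (1.55), Abcd2 (1.26) and Cyp17a1 (1.25). Slco1a1, another male-biased gene, was at -3.56. As means of their probes, Susd4 was at -2.14, Slco1a1 at -2.18 and Abcd2 at 0.78.

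The lipid droplet list did not stand apart (median 0.04), but 5 of its 20 expressed genes were at least 2-fold higher. Cidea (2.99, intensity 106 in WT and 968 in ob/ob), Cidec (2.17), Vldlr (1.15) and Pparg, the receptor that drives fat storage (1.22), were among them. Fatty acid synthesis genes had a median of 0.24, with Scd2 at 1.96, Fasn at 1.09 and Acaca, the acetyl-CoA carboxylase, at 0.88. Cholesterol synthesis genes were lower as a list (median -0.38, 0 of 14 at least 2-fold apart), led by Tm7sf2 (-0.98) and Stard4 (-0.72). Mitochondrial and peroxisomal beta-oxidation lists had medians of -0.07 and -0.01, and other PPAR-alpha targets -0.26, with Angptl4 at -0.75.

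Macrophage markers had a median of 0.70, with C1qb (1.32), Cd14 (1.23) and Vsig4 (1.11) at least 2-fold higher. Stellate cell markers had a median of 0.56 (up to 1.03 among the alternatives), with Col1a2 at 1.57, Vim at 1.11 and Acta2, the smooth muscle actin of activated stellate cells, at 1.96, or 0.44 as the mean of its probes. Amino acid and urea cycle genes were lower as a list (median -0.25), with Oat at -1.02 and Prodh at -0.95. The stress response list was at -0.29, with Creld2 at -1.35 and Sdf2l1 at -1.08, and was at 0.09 under the stricter filter on dim genes. Cell cycle genes had a median of 0.23 (0.07 at the weakest alternative), with Cdkn1a, a cell cycle inhibitor, at 1.30. Cbr3 (3.00) and Gstm3 (2.37), NRF2 targets, and Igfbp2 (-2.32), a leptin-responsive binding protein for insulin-like growth factors, were outside lists that stood apart.

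In all, 86 genes were at least 2-fold higher and 149 lower, with 5 lists standing higher and 4 lower. Against members of the other fixed lists, fatty acid synthesis genes and macrophage, stellate cell and female-biased markers remained higher, and cholesterol synthesis and male-biased genes lower. Without normalization, Vldlr (0.94), Pparg (0.97), Fasn (0.82), Vsig4 (0.77), Vim (0.86) and Cyp17a1 (0.94) were below 2-fold. The counts were 47 and 202 without normalization and 48 and 198 with each array centred on its median. Krtap7-1 (6.47) and Entpd6 (4.48) were among the highest genes, and E2f7 (-4.83) among the lowest; each rested on a probe at least 4-fold brighter on 1 array than on any other. The olfactory receptor median was 0.01, but 9 of 168 expressed olfactory receptor genes were at least 2-fold lower and 0 higher. Olfr355 (-3.12), Olfr24 (-3.07), the taste channel gene Trpm5 (-4.04, or -2.12 as the mean of its probes) and Mc1r, the melanocortin receptor of pigment cells (-3.82), were among the lowest genes.

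**Figure D1:**
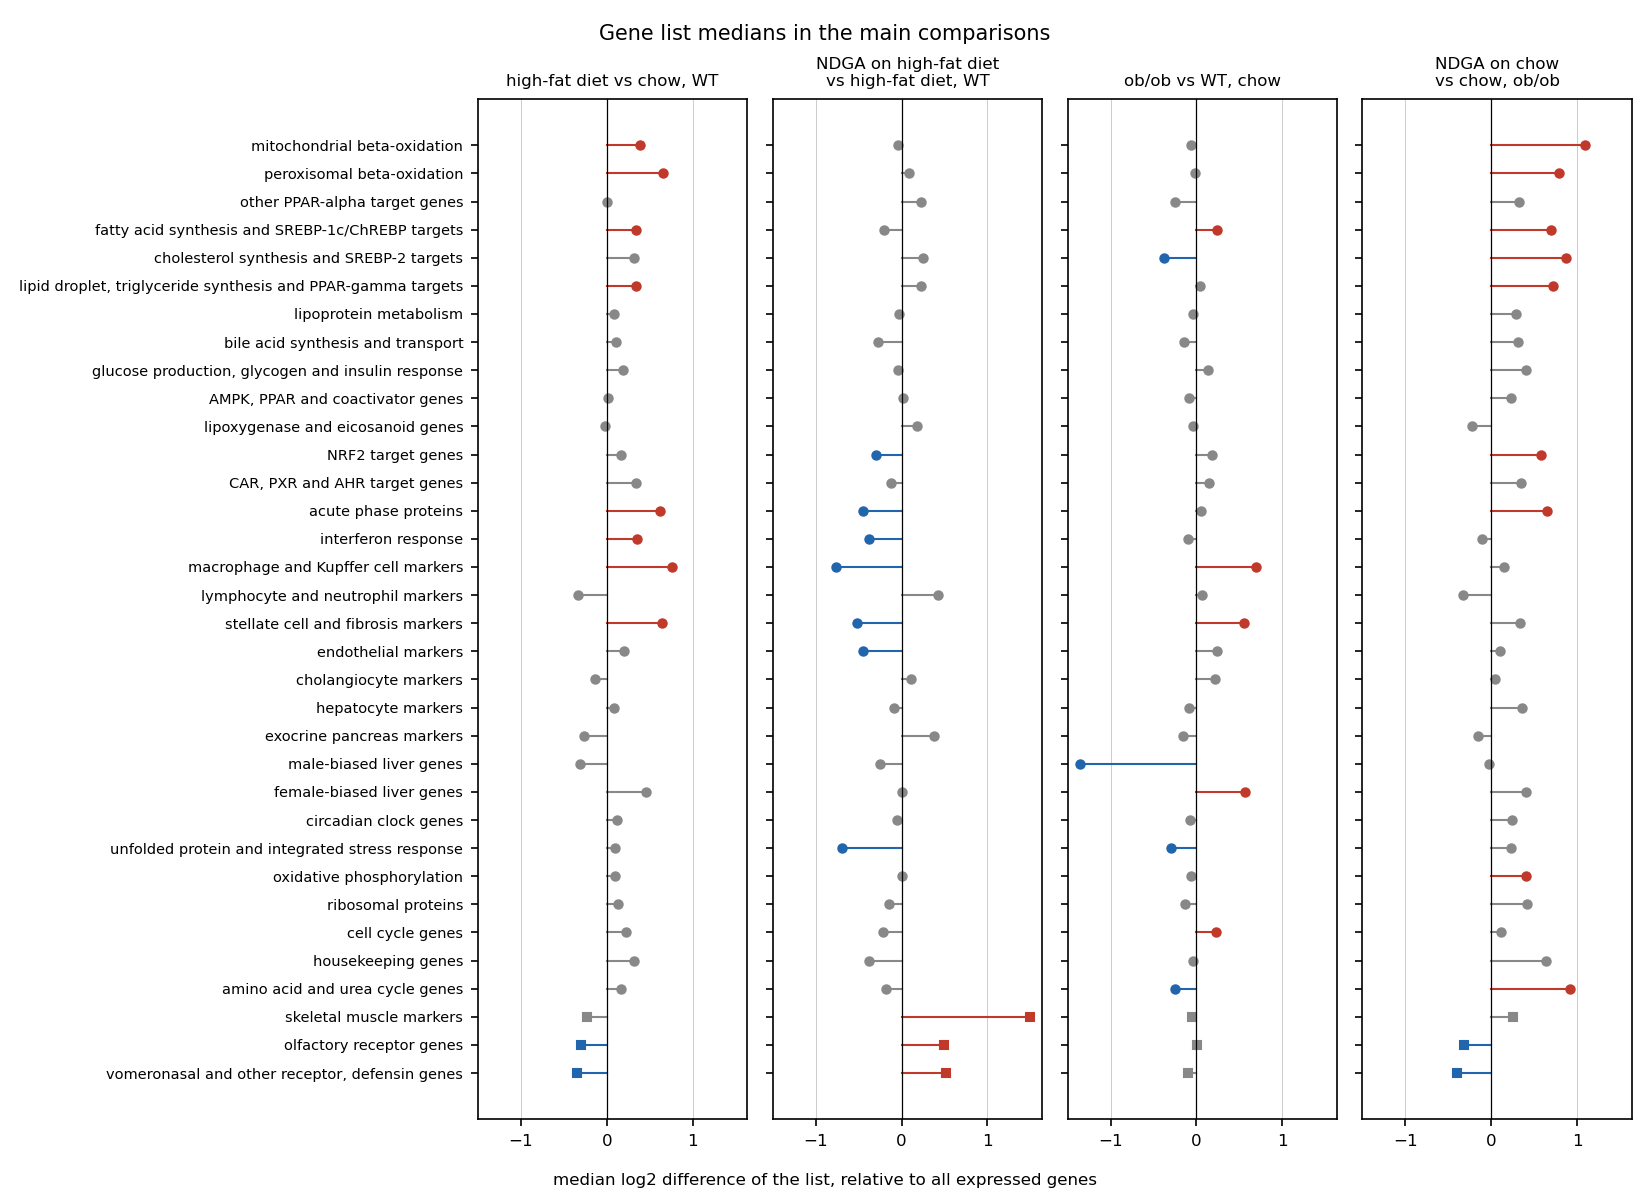
Median log2 difference of each gene list relative to all expressed genes (x axis) in the 4 comparisons; circles are lists fixed in advance, squares are lists added later, red marks lists standing higher, blue lower and grey neither. The keratin list and lists with fewer than 5 expressed members are left out; olfactory receptor genes lie at -0.30, 0.50, 0.01 and -0.32.

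NDGA on chow against chow in ob/ob asks whether NDGA changed liver expression in genetic obesity. Genes of fatty acid oxidation, lipid synthesis and amino acid breakdown were higher with NDGA. Cyp4a14 was 5.05-fold higher (log2 difference 2.34, intensity 663 on chow and 6970 with NDGA), Ehhadh was higher by 1.57 and Cyp7a1 by 1.57. Cidea was higher by 1.94, Igfbp1, a binding protein for insulin-like growth factors, by 1.99, and Cps1, the first enzyme of the urea cycle, by 1.72. Osgin1, an NRF2-responsive gene, was lower by 2.34 (-2.34). Without normalization Cyp4a14 was at 3.30, Ehhadh at 2.33, Cyp7a1 at 2.32, Cidea at 2.94, Igfbp1 at 2.77, Cps1 at 2.74 and Osgin1 at -1.35. The highest gene was Olfr1338 (6.07, intensity 4.70 on chow and 5386 with NDGA), and Miip (2.72) and Col6a3 (2.24, or 0.81 as the mean of its probes) were also among the highest. Krtap7-1 (-6.30), Entpd6 (-5.04) and Slc39a2 (-3.34) were the lowest, below Osgin1. Olfr1338, Miip, Col6a3, Krtap7-1, Entpd6 and Slc39a2 each rested on a probe at least 4-fold brighter on 1 array than on any other.

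Of 15 expressed mitochondrial beta-oxidation genes, 8 were at least 2-fold higher and 0 lower (median 1.09), among them Acads (1.56), Eci1 (1.30) and Cpt2 (1.18); Hadh was at 1.51, or 0.67 as the mean of its probes. Peroxisomal genes had 7 of 16 at least 2-fold higher (median 0.79), with Decr2 at 1.81, Acot4 at 1.52 and Pex11a, a peroxisome proliferation factor, at 1.32. Other PPAR-alpha targets had a median of 0.32 with 1 of 12 at least 2-fold higher; Angptl4 was at 0.89 and Fabp1 at -0.53, or 0.54 without normalization. Amino acid and urea cycle genes had a median of 0.92 with 6 of 18 at least 2-fold higher, including Gnmt (1.52), Hgd (1.35) and Aass (1.28). Oxidative phosphorylation genes had a median of 0.40, with Atp5a1 at 1.37 and Sdhb at 1.14; the list stood apart under only 5 of 10 alternatives, and housekeeping genes had a larger median (0.63) that did not stand apart.

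Cholesterol synthesis genes had a median of 0.87 with 5 of 14 at least 2-fold higher, such as Msmo1 (1.80), Tm7sf2 (1.62) and Nsdhl (1.39). Fatty acid synthesis genes had a median of 0.70, with Fads1 at 1.26, Scd2 at 1.17 and Acly at 1.12, and lipid droplet genes 0.72, with Mogat1 at 1.57 and Plin4 at 1.41. Acute phase proteins were at 0.65, with Mt2 at 1.88, Itih3 at 1.38 and Lcn2 at 1.12. NRF2 targets were at 0.58 (0.22 at the weakest, apart under 7 of 10 alternatives), with Srxn1 at 1.43 and Gstm3 at 1.40. Bile acid genes did not stand apart (median 0.31), but Abcb4, the phospholipid exporter, was at 1.65 and Abcc3 at 1.45. Gys2, the liver glycogen synthase, was at 1.26. Lipoxygenase and eicosanoid genes had a median of -0.23, with Cyp4f14 at -1.16 and Alox5 at -0.67, or -0.09 and 0.05 without normalization.

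In all, 561 genes were at least 2-fold higher and 42 lower, and 9 lists stood higher and 0 lower. Olfactory receptor genes had a median of -0.32, the second foreign receptor set -0.40 and muscle markers 0.25. Without the filter on dim genes these were at -0.08, -0.03 and 0.13. The array with NDGA was the brightest; counts were 1240 and 6 with median centring, and 2696 and 5 without normalization. Against members of the other fixed lists, mitochondrial beta-oxidation and amino acid genes remained higher, and lipoxygenase and eicosanoid genes and lymphocyte and neutrophil markers (median -0.33) stood lower.

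**Figure D2:**
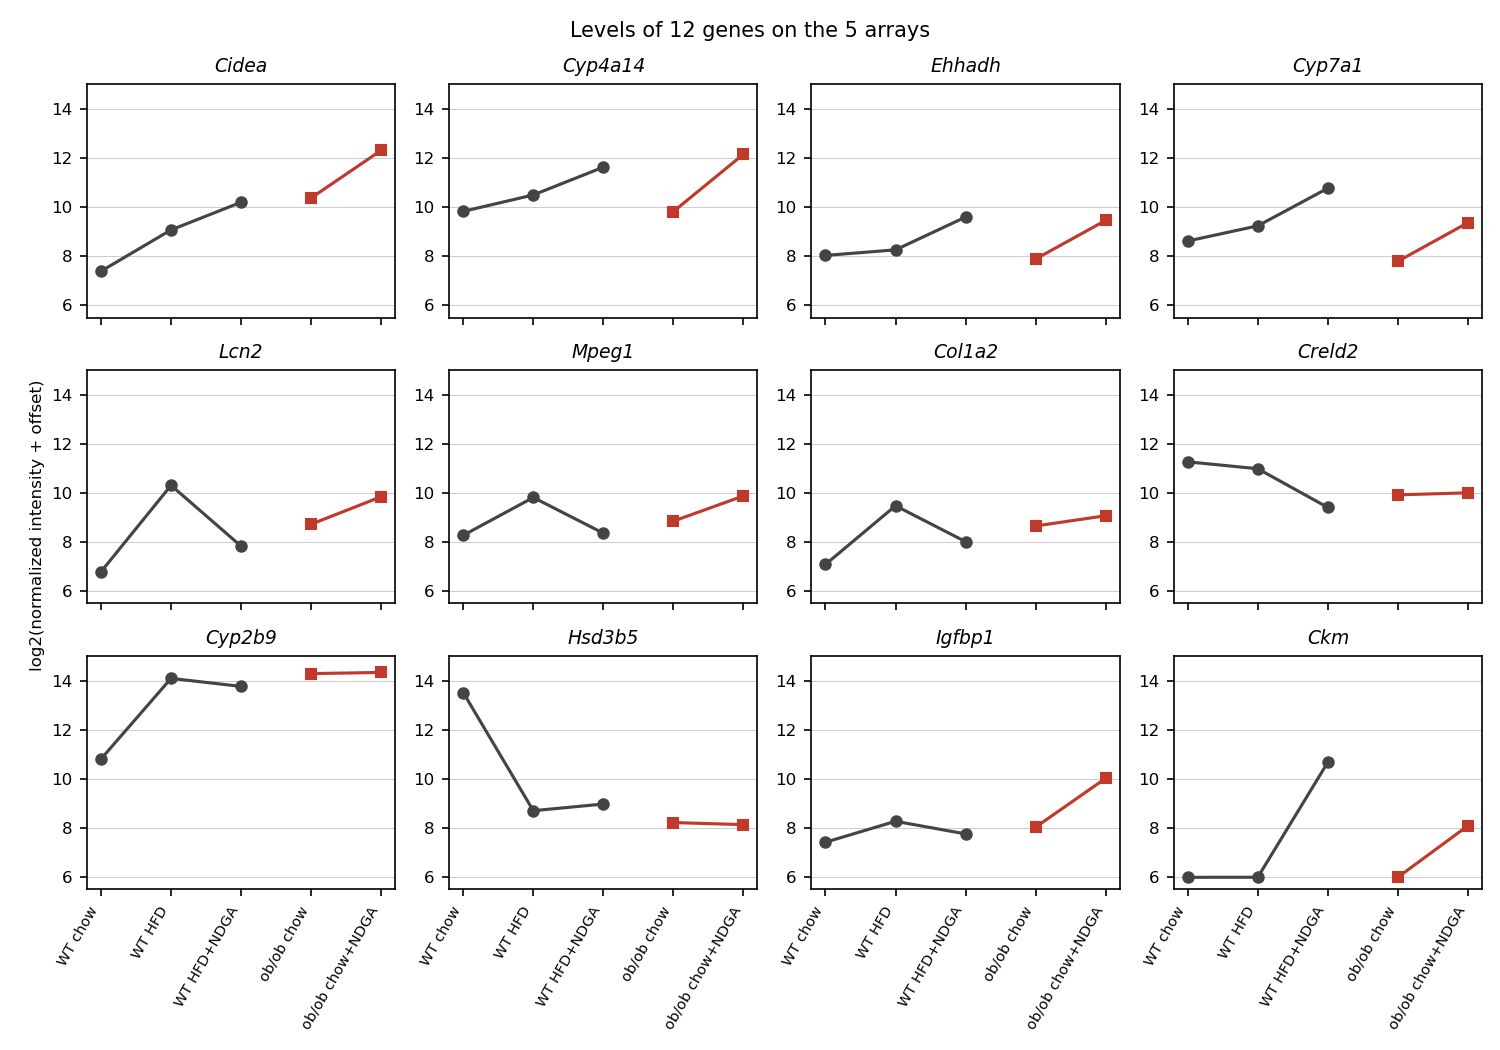
Levels of 12 genes, as log2 of normalized intensity plus the offset (y axis), on each of the 5 arrays (x axis; dark circles WT, red squares ob/ob, 1 array per point, lines only join arrays of 1 strain). Cyp4a14 lies at 10.50 on WT high-fat diet and 11.63 with NDGA, and at 9.82 on ob/ob chow and 12.16 with NDGA.

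The comparisons were set against each other in 6 pairs, over the 8319 genes whose mean over all 5 arrays reached the median; this filter differs from that of a single comparison, and passes 69 genes higher and 127 lower with NDGA in WT and 544 higher and 41 lower in ob/ob. The NDGA differences of both models shared no array. Across these genes they correlated at r = -0.54 (Spearman -0.63), and at -0.20 across 426 genes of the fixed lists; genes are not independent replicates. There were 11 genes at least 2-fold higher with NDGA in both models, where independent lists would share 4.51. Of these, Ckm, Cox6a2, Ckmt2, Mylpf and Mb are muscle genes, with differences in ob/ob of 2.10, 1.70, 1.63, 1.59 and 1.29. Ckm, Cox6a2 and Ckmt2 did not count as expressed for NDGA in ob/ob alone. They passed here on a mean that includes their bright WT high-fat NDGA array. Cyp7a1, Ehhadh, Cyp4a14, Cidea, Cfd (1.95 in WT and 1.18 in ob/ob) and Pltp (1.10 and 1.05), a phospholipid transfer protein of lipoproteins, made up the rest. The number was 18 without normalization, 4 with the stricter filter and 6 without the muscle genes. Without normalization far more genes were higher in ob/ob, so independent lists would share more than 4.51. The 18 is therefore no sign of a larger overlap. Osgin1 (-1.49 and -2.34), Sdr9c7 (-1.72 and -1.29) and Id3 (-1.04 and -1.20) were lower in both, where independent lists would share 0.63. Without normalization or with median centring only Osgin1 stayed so (-1.35 and -1.81 in ob/ob). Sdr9c7 in ob/ob was then at -0.47 and -0.92, and Id3 at -0.13 and -0.59. As the mean of its probes Sdr9c7 was below 2-fold in both models, at -0.87 in WT and -0.51 in ob/ob.

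**Figure D3:**
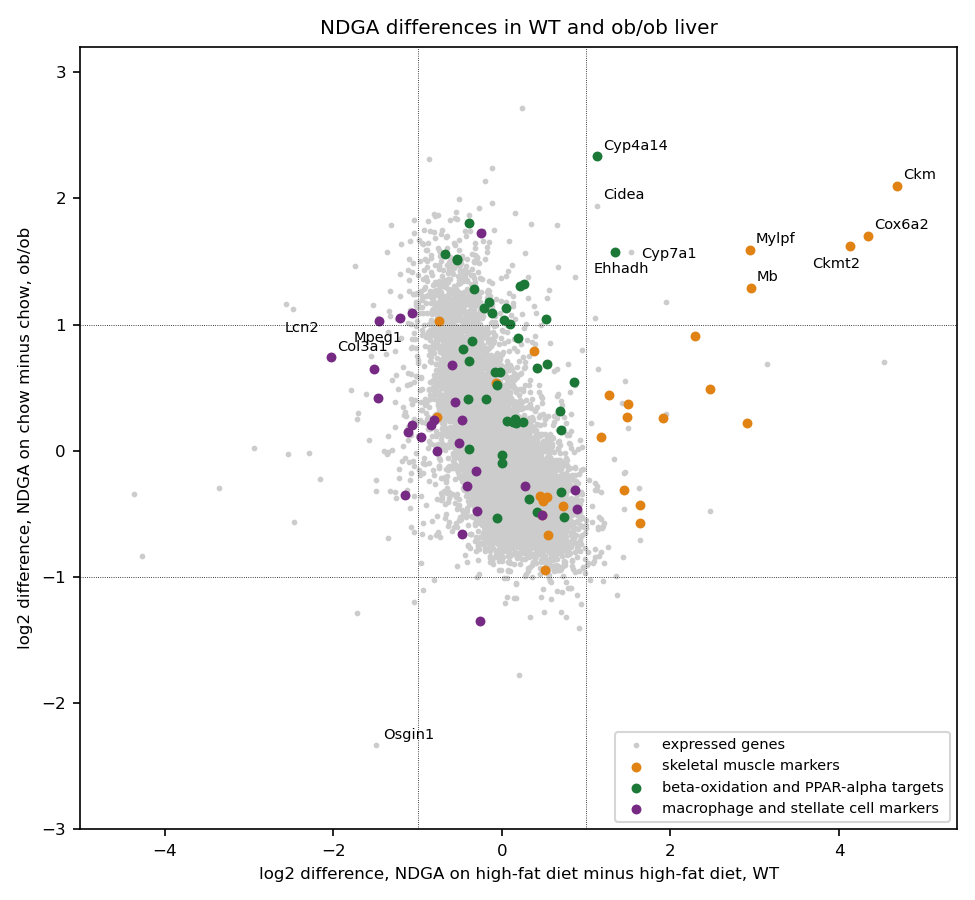
Log2 difference with NDGA in WT mice on high-fat diet (x axis) against that in ob/ob mice on chow (y axis); each point is a gene, coloured by list, and dotted lines mark a difference of 1. Most genes lie along a falling diagonal (r = -0.54), while Cyp4a14, Ehhadh, Cyp7a1, Cidea and 5 labelled muscle genes lie to the upper right.

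Both forms of obesity were compared with the same WT chow array. Their differences correlated at r = 0.52, beside 0.50 simulated for a shared array with equal noise on every array and no effect (covariance 0.10). In both, 44 genes were at least 2-fold higher, where independent lists would share 1.83, (29 without normalization), and 78 lower, where they would share 1.88; the shared array adds to both numbers. Among the genes that the rule names in both were Cyp2b9, Cidec, Cidea, Anxa2 and Gstm3 on the higher side. On the lower side were Hsd3b5, Slco1a1, E2f7, Pp2d1, Mc1r (-2.34 with high-fat diet and -3.82 in ob/ob) and Trpm5 (-2.02 and -4.04). Hsd3b5 and E2f7 rested on probes at least 4-fold brighter on the shared WT chow array than on any other. Olfactory receptor genes such as Olfr355 (-1.65 and -3.12) were also among the 78. NDGA in WT correlated at r = -0.20 with ob/ob against WT, with which it shares no array. There were 24 genes lower with NDGA and higher in ob/ob, where independent lists would share 1.31, and Col3a1, Lcn2, C1qb, Vim and Anxa2 were among them. Another 16 genes were higher with NDGA and lower in ob/ob, where independent lists would share 1.21. In the same direction, 1 gene was higher and 4 were lower in both. NDGA in ob/ob correlated at r = 0.63 with high-fat diet against chow (0.46 across 426 genes of the fixed lists), again without a shared array. In both, 80 genes were higher and 12 lower, where independent lists would share 11.57 and 0.53. The 80 became 147 without normalization, where independent lists would share more, and 61 with the mean of probes. The 12 became 0 without normalization or with median centring, and 5 with loess. Only 1 gene went opposite ways (8 without normalization). Olfactory receptor medians also went the same way in both comparisons (-0.30 with high-fat diet, -0.32 with NDGA in ob/ob). A difference in nonspecific signal may account for part of this likeness. The pairs that share an array gave r = -0.71 for NDGA in WT with high-fat diet and -0.09 for NDGA in ob/ob with ob/ob against WT, beside -0.50 simulated with no effect for both. The simulation gave every array equal noise, but the SD of the difference between 2 arrays ran from 0.35 to 0.68. The value with no effect depends on the noise of each array. Correlations of pairs that share an array therefore cannot show an effect beyond the shared array.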

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

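The tests on brightness, on muscle genes and on single bright probes were chosen only after the results were seen; that on the second foreign receptor set was written before its result.

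NRF2 target genes and acute phase proteins went opposite ways with NDGA in the models. The NRF2 median was -0.30 in WT and 0.58 in ob/ob, and the acute phase median was -0.45 in WT and 0.65 in ob/ob. The NRF2 list stood apart under 6 of 10 alternatives in WT and 7 of 10 in ob/ob, the acute phase list under 10 of 10 in both, and neither did against the other fixed lists. No normalization and median centring are the same test for a list, so these are not 10 separate checks. At the gene level, 40 genes were at least 2-fold lower with NDGA in WT and higher in ob/ob, where independent lists would share 8.30, and 3 went the other way, among genes whose mean over all 5 arrays reached the median. Tsc22d1 (-1.74 and 1.46), Sprr1a (-1.37 and 1.57), Yipf5 (-1.32 and 1.79) and Cyp2d9 (-1.33 and 1.26) were among the 40, and Rtn4rl2, Tesc and Nwd1 made up the 3. The 40 became 54 without normalization, 76 with median centring, 73 with an offset of 16, 36 with loess, 35 with the mean of probes and 26 with the stricter filter, and the 3 became 0 without normalization, with median centring or with loess. Without normalization or with median centring many more genes were higher in ob/ob, so independent lists would share more than 8.30. The rise to 54 and 76 is therefore no sign of a stronger result. These results drew attention because the direction differed between models given the same dose of NDGA. The WT mice were on high-fat diet and the ob/ob mice on chow, so genotype and base diet cannot be told apart. With 1 array per group the difference was not tested.

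Many liver pathway lists shared a direction within each of 3 comparisons, and receptor families foreign to liver went the opposite way, both relative to all expressed genes. If the arrays differ in nonspecific signal, a second foreign set should shift as the olfactory receptors did, and it did so in 3 of 3 comparisons, at -0.35, 0.52 and -0.40. These medians cover only the 20 or 21 of its 137 named genes that passed the filter on dim genes. Without that filter they were -0.06, 0.09 and -0.03, and those of the olfactory receptors -0.06, 0.13 and -0.08. A broad true shift of liver genes would also move both foreign sets the other way relative to all genes, so this test cannot separate these explanations. For NDGA in ob/ob without normalization, the median of all genes was 0.68 and the olfactory median -0.43 relative to it. Foreign probes were thus not dimmer there before scaling. A trend of the difference with brightness is argued against, since the olfactory median was within the central 95% of random lists matched on brightness in 0 of 3 comparisons, and stayed at -0.30, 0.51 and -0.33 after a loess on brightness. A difference between arrays in nonspecific signal may account for part of the shared direction, and for part of the opposite NDGA response in the models. An effect of diet or NDGA on these pathways stays open, as do RNA quality and labelling, which were not tested; in ob/ob against WT the olfactory median was 0.01, although 9 of 168 olfactory receptor genes were at least 2-fold lower and 0 higher.

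Many skeletal muscle genes, but not all, were higher on the array of WT mice on high-fat diet with NDGA. Tnnt3 (-0.76), which was at 3.12 in ob/ob against WT, and Car3 (-0.74) were lower. Of the 17 expressed genes at least 2-fold higher, 7 read under 50 on WT chow. Tnnc2 (859 on WT chow) and Myh2 (311) were bright there and lower with high-fat diet (-1.34 and -1.39). Car3, Tnnc2 and Myh2 were chosen after their values were seen. Muscle tissue or its RNA in the sample would raise most muscle genes, and 40.4% of the 47 named on the array were at least 2-fold higher, which leaves it open. This test replaced the share of expressed muscle genes (60.7% of 28), since the filter admits genes because they are high with NDGA. A response to NDGA common to both models would raise the same genes in ob/ob, and 35.3% of the 17 expressed genes at least 2-fold higher in WT were so there. Among those, Ckm, Cox6a2, Ckmt2 and Fabp3 did not count as expressed in the ob/ob comparison. An earlier test on the list median in ob/ob (0.25, within random lists) was replaced by this share. Muscle RNA in the sample and a response of liver cells cannot be told apart, because 1 array per group gives no other sample to compare.

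Several of the largest differences came from probes bright on 1 array. There were 36 probes at least 4-fold above the next array: 9 on WT chow, 10 on high-fat diet, 11 on high-fat diet with NDGA, and 3 on each ob/ob array. A fault of single spots would leave other probes of the same genes low, and 0 of 13 such probes were at least 2-fold higher on that array. That decides nothing, since among genes with 2 bright probes and 1 past 2-fold, both were past it in only 21 of 216, or 9.72%. A spot fault and a true difference cannot be told apart for genes such as Bcl3, Plau, Krtap7-1, Entpd6 and Hsd3b5. For muscle genes a spot fault is argued against, since 3 of 4 with such probes, Ckm, Cox6a2 and Ckmt2, were also at least 2-fold higher with NDGA in ob/ob on separate arrays (2.10, 1.70 and 1.63). These 3 did not count as expressed in the ob/ob comparison. They read 316, 276 and 251 with NDGA and 12.4, 21.4 and 20.5 without. Ryr1 (0.22) stays open.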

How the results depend on the processing

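The tests with another offset, without saturated probes, without muscle genes and against other fixed lists were chosen only after the results were seen. Without normalization the median of all genes was 0.68 for NDGA in ob/ob and -0.15 for ob/ob against WT (0.22 and -0.13 with median centring), so gene counts there follow the scaling while list medians are relative to it. Genes at least 2-fold higher for ob/ob against WT were then 47 (48 with median centring), and for NDGA in ob/ob 2696 higher and 5 lower (1240 and 6); with loess 19 were lower. The filter at the 75th percentile, which tests fewer genes, left 115 higher for high-fat diet, 45 for NDGA in WT and 308 for NDGA in ob/ob, with 5 lists higher, 4 lower for NDGA in WT and 2 lower for ob/ob; it reversed the stress response list in ob/ob (0.09). The cause of that reversal was not tested. Against other fixed lists, 3 lists were higher and 1 lower for high-fat diet, 3 lower for NDGA in WT, 4 higher and 2 lower for ob/ob, and 2 higher and 2 lower for NDGA in ob/ob. Of the lists standing apart, 4 of 8, 3 of 7, 4 of 5 higher and 2 of 4 lower in ob/ob, and 7 of 9 did so under all other alternatives run. In all, 1210 of 1223 alternative list medians moved by less than the half-width of random lists and 12 by more. Of 3687 values of named genes, 3545 stayed on their side of 2-fold and within 1 log2 unit, and 142 did not. The filters and leaving out muscle genes cannot change a gene's own difference, so their values could not move. All moves came from no normalization (43), median centring (35), loess (12), the mean of probes (36) and the offset of 16 (16). The sign differed for 8 values of 6 genes, 0 of them at least 2-fold apart: Fabp1 (0.54 and 0.08), Alox5, Cysltr1 and Alox5ap for NDGA in ob/ob, Hadh for NDGA in WT, and Lep, near background, for both. Correlations across genes moved by under 0.1 in the settings run, which left out median centring and the floor. No paired analysis was possible because each group has 1 array. Between 45.1% and 54.1% of probes lay below the offset, where differences are compressed.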

Other observations

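The tests and comparisons of levels in this part were chosen after the data were seen.

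Against random lists, sex-biased lists stood apart in ob/ob against WT only; with high-fat diet the male-biased median was -0.31, lower against the other fixed lists, and the female-biased median 0.45. Hsd3b5, on a probe at least 4-fold brighter on WT chow than on any other array, read 13.52 (log2) on WT chow and between 8.13 and 8.97 on the other 4 arrays, and Cyp2b9 read 10.81 on WT chow and 13.77 to 14.34 on the others. The male-biased median was -0.25 with NDGA in WT and -0.03 in ob/ob, and the female-biased median 0.00 and 0.41, none of them apart from random lists; the differences between comparisons were not tested. Cidea, by contrast, was higher at each step, from 7.39 on WT chow to 9.07 on high-fat diet and 10.20 with NDGA, and from 10.38 on ob/ob chow to 12.32 with NDGA. Lepr, the leptin receptor gene, was at 0.78 with high-fat diet, -0.87 with NDGA in WT, 0.33 in ob/ob and 0.94 with NDGA in ob/ob.

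Cell type and housekeeping lists that stood apart from random lists in no comparison had medians over the 4 comparisons of -0.09 to 0.35 for hepatocyte markers, -0.14 to 0.22 for cholangiocyte markers, -0.34 to 0.42 for lymphocyte and neutrophil markers, -0.27 to 0.37 for exocrine pancreas markers, -0.38 to 0.63 for housekeeping genes and -0.15 to 0.41 for ribosomal proteins. Adipocyte and erythroid lists had fewer than 5 expressed members and no median. Lipoprotein metabolism ranged from -0.04 to 0.29, bile acid genes from -0.28 to 0.31, glucose and glycogen genes from -0.04 to 0.40, AMPK, PPAR and coactivator genes from -0.09 to 0.23, circadian clock genes from -0.08 to 0.24, lipoxygenase and eicosanoid genes from -0.23 to 0.18, CAR, PXR and AHR targets from -0.13 to 0.35 and other PPAR-alpha targets from -0.26 to 0.32. Keratin genes, which were added later, were at -0.22, 0.42, 0.05 and -0.40 in the order high-fat diet, NDGA in WT, ob/ob and NDGA in ob/ob.

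The arrays of WT on high-fat diet and of ob/ob on chow with NDGA were alike (r = 0.978 across genes, 143 genes at least 2-fold apart), as were those of WT on chow and WT on high-fat diet with NDGA (r = 0.980, 119 genes). WT on chow and ob/ob on chow with NDGA were least alike (r = 0.925, 868 genes). Olfactory receptor medians split these 4 arrays the same way (-0.30 for high-fat diet, 0.50 for NDGA in WT and -0.32 for NDGA in ob/ob). A difference in nonspecific signal may account for part of these likenesses, which was not tested.

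Among unnamed probes bright enough to count, 31 were at least 2-fold higher and 69 lower with high-fat diet, 24 and 28 with NDGA in WT, 14 and 76 in ob/ob, and 105 and 14 with NDGA in ob/ob.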
